A study of Mus musculus with 28 samples.

How the data were processed

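Of the 28 samples of the series, 14 were chromatin immunoprecipitation (ChIP) or input samples and 14 were RNA samples. The 11 ChIP samples with a peak list were used: CTCF (2), Rad21 (2) and Ldb1 (3) in control mature olfactory sensory neurons, and Ldb1 in Lhx2 KO neurons (2) and in cells sorted on Olfr1507 (2). The 3 input samples and the RNA samples were not analysed here. For 2 RNA samples from Krt5Cre mice the labels disagree on whether bright or dim cells were sorted, and they were given no group.

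Per the labels' protocols, cells were fixed with formaldehyde before sorting, chromatin was sheared by sonication, and libraries were made from immunoprecipitated DNA with a low-input kit. The submitters' processing notes list cutadapt 1.9.1, Bowtie2 2.3.2, STAR 2.5.3a, SAMtools 1.3.1, Picard and HOMER 4.7, and the genome build mm10, without the role of each. The peak threshold, the control library and any filters are not given in the sources used here. Each deposited list belonged to 1 library, so peaks were not pooled over replicates. Within a list the peaks had 1 width, from 212 to 380 bases, except for 1 peak of the first CTCF library. The score of each peak is the authors' own value as deposited, a whole number whose scaling between libraries is unknown, and it was used only to rank peaks within a list. Averages of scores over the libraries of a group served only to order regions of that group. With no read numbers the depth behind a peak is unknown; a short list can come from little binding, little enrichment or few reads.

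Peaks on chromosomes 1 to 19, X and Y were kept. A region is a set of linked peaks (overlap of at least 1 base) that holds peaks of at least 2 libraries of a group. Control Ldb1 regions were ranked by the mean percentile of the score within each list, an absent peak counting as 0, and divided into 10 bins. Gene positions came from a RefSeq table of assembly GRCm38.p6, the build called mm10 in the notes. It holds gene starts and ends but neither strand nor exons, and 340 genes on scaffolds, whose coordinates ended before 3 Mb, were left out. An OR cluster is a run of at least 3 OR genes or pseudogenes with gaps up to 300 kb, extended by 100 kb on both sides. No genome sequence was used here, so the planned search for the LHX2 motif was not run.

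Overlaps with other regions and with OR clusters were tested by moving 1 set along each chromosome by a random distance, wrapped at the ends (1000 shifts, two-sided, smallest p 0.002; 200 shifts for the alternatives). Counts of regions were compared with Fisher's exact test, and within bins of control score by a Mantel-Haenszel odds ratio with 10000 permutations. Regions are not replicates, and neighbouring regions are not independent. Libraries are the replicates where groups are compared: differences of library means were tested by exact permutation of the 5 libraries, whose 10 assignments allow no p below 0.1. Intervals of odds ratios and shares are 95% (Woolf and Wilson) and cover counting error only. A gene was given a region if a control Ldb1 region overlapped its body extended by 10 kb, and 15 gene lists were compared with all other protein-coding genes; 1 listed symbol was not found in the table. All 3 control Ldb1 libraries serve both the Lhx2 KO and the Olfr1507 comparison, which therefore share their chance deviations.

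The groups, tests, lists and the other settings to try were fixed before the data were examined. As an exception, the OR gene list was planned with pseudogenes and tested without them. The rule for named items was also fixed before the data were examined. It takes up to 4 members per gene list by the score of the strongest region within 10 kb, the 10 strongest regions of each group, the 10 strongest Ldb1 regions in OR clusters, and outside OR clusters the 10 strongest found in both KO libraries and the 10 strongest found in neither, of which 1 is not reported here. Olfr1507, Lhx2, Ldb1, Omp, Adcy3, Rtp1, Kdm1a, Ebf1 and Emx2 were always looked up. Cngb3 and Olfr1357 fall outside this rule and were chosen after their values were seen, as the single list member without a region and as a neighbour of a peak.

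The tests were tried on simulated data. Over 22789 regions moved at random, planted ratios of 0.5 and 4 in OR clusters were recovered as 0.504 and 3.64 and called in 20 of 20 runs each, and a ratio of 1 was called in 0 of 20. A planted odds ratio of 4 in the retention test was recovered as 3.97 and called in 100 of 100 runs, and an odds ratio of 1 in 4 of 100. For a list of 20 genes among 21779, an odds ratio of 8 was recovered as 8.44 and called in 100 of 100 runs, and 1 in 3 of 100. The simulated regions and genes were drawn independently. Neighbouring regions in the data are not independent, so these rates of calls need not hold for the real lists. Alternatives covered the overlap rule (reciprocal overlap of at least 50%, or centres within 200 bases), the top-scoring part of each list, leaving out each library, other definitions of a region and of an OR cluster, another background and another gene window. Random genes of the same length (20 length bins, 10000 draws) were added as a background for the gene lists after seeing the data. The comparisons of the strongest 10% of regions, of regions near each gene list in the KO and Olfr1507 libraries, of the strongest regions among equal numbers of top peaks and of single Rad21 libraries were also chosen after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.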

Results

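The series mapped the binding of 3 proteins in mouse mature olfactory sensory neurons, the cells of the nose that each express 1 odorant receptor (OR) gene out of a family of more than 1000. CTCF is a DNA-binding protein found at domain boundaries, Rad21 is a subunit of the cohesin ring, and Ldb1 is a cofactor that binds no DNA itself and is held on chromatin by partners such as the LIM-homeodomain factor Lhx2. Cells were dissociated from the olfactory epithelium, fixed with formaldehyde and sorted before chromatin immunoprecipitation and sequencing. CTCF (2 libraries), Rad21 (2 libraries) and Ldb1 (3 libraries) were mapped in control neurons marked by a GFP reporter at Omp, a gene of mature neurons. Ldb1 was mapped again in 2 libraries from neurons that had lost Lhx2 after Omp-driven recombination (Lhx2 KO), and in 2 libraries from neurons sorted on a GFP reporter for a single receptor, Olfr1507. The labels do not say whether libraries of a group came from separate animals, so p-values over libraries measure the spread between these libraries, which may be technical. The 14 RNA samples and 3 input samples of the series were not analysed here.

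The peak lists differed widely in length. The control Ldb1 lists held 24877, 28879 and 16067 peaks on the main chromosomes, the CTCF lists 27609 and 34210, and the Rad21 lists 10487 and 28151. The Lhx2 KO lists were far shorter, with 4290 and 542 peaks, and the Olfr1507 lists held 5095 and 21250. Sequencing depth is unknown, since the lists carry no read numbers. Peaks seen in at least 2 libraries of a group gave 22789 control Ldb1 regions, of which 14851 were in all 3 libraries, 24877 CTCF regions, 9881 Rad21 regions, 393 Lhx2 KO Ldb1 regions and 4989 Olfr1507 Ldb1 regions. Of the peaks of the second Lhx2 KO library, 72.5% overlapped a peak of the first (393 of 542), and 97.9% of the peaks of the first Olfr1507 library overlapped one of the second.

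Whether cohesin lay at CTCF sites in these neurons was examined first. Most regions shared by both Rad21 libraries did: 9143 of 9881 Rad21 regions (92.5%) overlapped a CTCF region, against 70.9 ± 8.80 (SD over 1000 shifts) when the regions were moved along their chromosomes, a 129-fold excess (circular shift permutation test, two-sided p = 0.002, the smallest that 1000 shifts can give). The share depended on the library, as 9436 of the 10487 peaks of the first and 16336 of the 28151 peaks (58.0%) of the second Rad21 list lay at a CTCF region. The Rad21 region with the highest mean score lay on chromosome 10 from 79925351 to 79925663, 1.26 kb from Kiss1r. Other strong Rad21 regions with a CTCF peak in both libraries lay in Fmnl3, Faap20 and Abca14, and 21.2 kb from Ebf2, which encodes a transcription factor of olfactory neurons. The strongest CTCF regions lay 1.98 kb from Dgat2 and within Ctif, Kmt2a and Sh3glb1.

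Most Ldb1 regions lay apart from sites where both libraries of CTCF or of Rad21 had a peak. Of the 22789 control Ldb1 regions, 21379 (93.8%) overlapped neither a CTCF nor a Rad21 region, 490 overlapped both, 539 CTCF alone and 381 Rad21 alone. The share rested on requiring both Rad21 libraries: 3.82% of the Ldb1 regions lay at a Rad21 region, but the second Rad21 library had a peak at 23.4% of the Ldb1 regions outside OR clusters and 12.6% of those inside. The overlaps were nonetheless above those of shifted regions, with 1029 Ldb1 regions at CTCF against 170 ± 13.3 (6.04-fold) and 871 at Rad21 against 65.8 ± 8.15 (13.2-fold, both p = 0.002, two-sided circular shift permutation test). Against all regions bound in any of the 11 libraries the log2 odds ratio was -4.25 for CTCF and -2.47 for Rad21, a sign set by that background, in which most sites without Ldb1 are there because CTCF or Rad21 bound them. Without the first Rad21 library the log2 excess at Rad21 was 4.87, against 3.73 with both, and without the first CTCF library it was 3.28 at CTCF, against 2.60.

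The strongest Ldb1 region of control neurons lay between genes on chromosome 5, from 33542129 to 33542466, 57.9 kb from Fam53a. It was followed by regions within Zfp64, Cmip, Lingo2, Gse1, Phactr1 and Acbd6, and by regions 0.636 kb from Ankrd10, 3.50 kb from Pars2 and 7.53 kb from Ciao3. Each of these 10 regions also held a peak in both Lhx2 KO libraries and in both Olfr1507 libraries. Gene bodies are given as the annotation lists them; exons and introns were not told apart.

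Genes that olfactory neurons use carried Ldb1 regions more often than other genes did. Compared with all other genes, without regard to gene length, 4 of the 5 lists with this excess were also rich in CTCF and Rad21 regions. Across 21779 protein-coding genes, 8634 (39.6%) had a control Ldb1 region within 10 kb of the gene body. In the olfactory transduction list 19 of 20 genes had one (exact adjusted p = 1.07e-06), with Cngb3 the exception, a member named after its values were seen. The strongest member was Gng13, a G-protein gamma subunit, with a region inside the gene on chromosome 17 from 25718304 to 25718643. Pde1c, a phosphodiesterase of cyclic nucleotides, had 21 regions over its 583 kb. Omp had 2, Ric8b, which encodes a partner of the olfactory G protein, had 8, and Adcy3, the adenylyl cyclase of olfactory cilia, had 10. The adjusted p-values for gene lists, called exact adjusted p, are from Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over the 15 lists. These were fixed before the data were examined, except that the OR list was planned with pseudogenes and tested on protein-coding genes alone.

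Regulators of these neurons showed the same excess, with 19 of 22 genes (log2 odds ratio 3.27, exact adjusted p = 2.15e-05). Ebf3 had 15 regions, Ebf1 26, Ebf4 6 and the homeobox gene Emx2 3. Lhx2 itself had 4 regions, and Kdm1a, a histone demethylase, had 1 weak region. All 24 axon guidance genes had a region (exact adjusted p = 1.11e-09), among them the semaphorin receptor genes Nrp1 and Plxna4, with 9 and 32 regions, and the ephrin genes Efna5 and Efna3, with 16 and 4. Of the immature neuron markers 11 of 12 had one (log2 odds ratio 4.07, exact adjusted p = 0.000620), including Gap43, Gng8, Ncam1 and Stmn2. Clustered protocadherin genes counted 36 of 57 (exact adjusted p = 0.000684), but these genes share long overlapping bodies and the 36 members rested on 5 regions. That call was lost against random genes of the same length, a comparison chosen after seeing the data (permutation adjusted p = 0.156). Genes of the 4 neuronal lists are long too, and random genes of the same length gave a mean of about 11 of 20 for olfactory transduction, 11.5 of 22 for regulators, 15.7 of 24 for axon guidance and 5.98 of 12 for immature markers. The excess over these was smaller than over all genes and stayed past the threshold (permutation adjusted p = 0.000750, 0.00400, 0.000750 and 0.00643). In the same order of lists 18, 19, 22 and 12 genes had a CTCF region (exact adjusted p = 0.00716, 0.0109, 0.00139 and 0.00681) and 17, 17, 19 and 9 a Rad21 region (exact adjusted p = 6.10e-06, 4.18e-05, 8.29e-06 and 0.00635). The CTCF and Rad21 counts were not compared with random genes of the same length, so gene length may account for their excess.

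**Figure D1:**
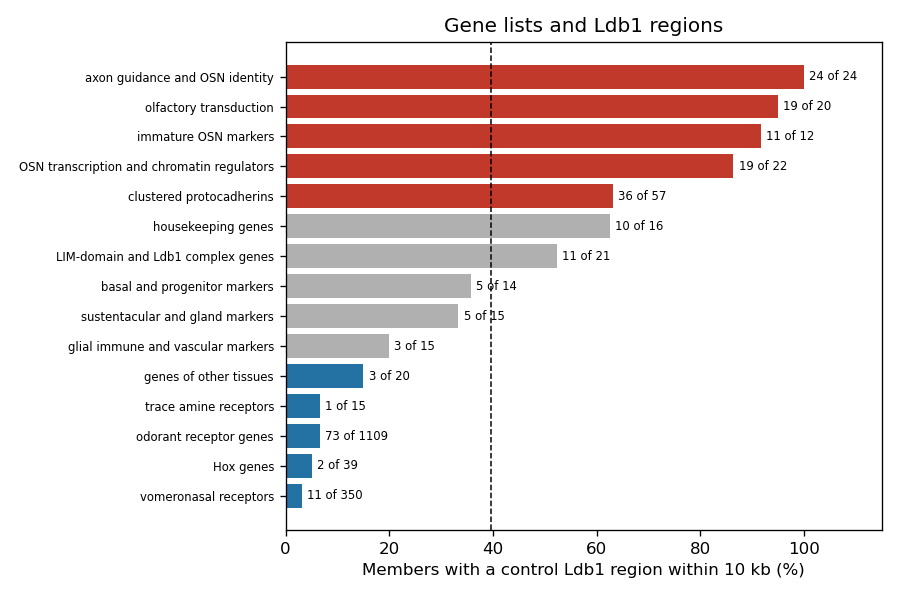
Share of the members of each gene list with a control Ldb1 region within 10 kb of the gene body, in percent, with the counts beside the bars. The dashed line is the share over all protein-coding genes (39.6%), red bars are lists with a higher share, blue bars are lists with a lower share (adjusted p under 0.05, Fisher's exact test) and grey bars are the others.

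Receptor gene families lay at the other end. Only 73 of 1109 protein-coding OR genes had an Ldb1 region within 10 kb (6.58%, log2 odds ratio -3.33), as did 11 of 350 vomeronasal receptor genes (log2 odds ratio -4.38), 1 of 15 trace amine receptor genes (Taar7d, exact adjusted p = 0.0122) and 2 of 39 Hox genes (log2 odds ratio -3.61). Genes of other tissues had 3 of 20 (exact adjusted p = 0.0346). CTCF and Rad21 regions were also few at OR genes (log2 odds ratios -5.29 and -5.09) and at vomeronasal receptor genes (-7.28 and -8.37). At trace amine receptor genes neither passed the test (-0.570 and -1.59). Only the Ldb1 counts were also compared with genes of the same length. These receptor genes are short: against random genes of the same length the deficit stayed past the threshold for OR genes (73 against 132 ± 8.54, SD over 10000 draws), vomeronasal receptor genes and Hox genes, and not for trace amine receptors (permutation adjusted p = 1.0) or genes of other tissues (permutation adjusted p = 0.321). The LIM-domain and Ldb1 complex list counted 11 of 21, with 3 regions at Ldb1 and 2 at Lhx4 (exact adjusted p = 0.308). Markers of other cells of the epithelium did not pass the test, with 5 of 14 for basal and progenitor cells, 5 of 15 for sustentacular cells and glands and 3 of 15 for glial, immune and vascular cells (exact adjusted p = 1.0, 0.850 and 0.232). Housekeeping genes had 10 of 16 (exact adjusted p = 0.101, and permutation adjusted p = 0.0390 against genes of the same length).

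OR genes lie in clusters, and the series concerns enhancement in trans by Ldb1, so the regions inside OR clusters were compared with those elsewhere. The 43 clusters held 1392 of the 1427 annotated OR genes and pseudogenes and covered 38.5 Mb with 100 kb flanks. They held 167 control Ldb1 regions against 374 ± 59.4 after circular shifts (log2 ratio -1.16), 190 CTCF regions against 425 ± 71.9 (log2 ratio -1.16) and 80 Rad21 regions against 173 ± 33.0 (log2 ratio -1.11; p = 0.002 for each, two-sided permutation by circular shifts). Compared with all bound regions instead, no factor passed the test (log2 odds ratios 0.034, 0.13 and 0.20, Fisher's exact p = 0.813, 0.331 and 0.276). Ldb1 regions were found in 41 of the 43 clusters. With the flanks left out, 91 Ldb1, 45 CTCF and 18 Rad21 regions remained. The log2 ratios were then -1.69, -2.89 and -2.92 (permutation p = 0.00995 for each, the smallest that 200 shifts give). These values were lower for CTCF and Rad21 than for Ldb1, but the difference between factors was not tested.

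Those few Ldb1 regions were strong more often than Ldb1 regions elsewhere. Of the 167 regions in OR clusters, 31 (18.6%) were among the 10% with the highest control score, against 9.94% elsewhere (log2 odds ratio 1.05, 95% interval 0.48 to 1.61, Fisher's exact adjusted p = 0.00263 over 4 tests). CTCF regions (8.42% against 10.0%, exact adjusted p = 0.707) and Rad21 regions (11.3% against 10.0%, exact adjusted p = 0.707) gave no such difference, and 9 of the 40 Olfr1507 Ldb1 regions in OR clusters (22.5% against 9.90%, exact adjusted p = 0.0303) were among the strongest 10% of that group. The 10 strongest lay within Lpxn on chromosome 19 (12830836 to 12831195, 30.6 kb from Olfr1444), and near Olfr9 (10.8 kb), Olfr1413 (26.8 kb), Olfr15 (57.4 kb), Olfr856-ps1 (5.53 kb), Olfr286 (28.9 kb), Olfr448 (26.3 kb), Olfr464 (22.2 kb), Olfr139 (7.85 kb) and Olfr523 (10.0 kb). None of the 10 held a CTCF peak in either library.

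The replicates of Rad21 disagreed at these sites. A peak of the first Rad21 library lay at 9 of the 10 (Olfr15 was the exception) and a peak of the second, longer list at 0. Among the strongest 10% of Ldb1 regions, the first library had a peak at 19 of 31 regions in OR clusters (61.3%) and at 270 of 2248 elsewhere, and the second at 4 of 31 (12.9%) and at 50.8% elsewhere. The log2 odds ratios were 3.54 (95% interval 2.48 to 4.59) and -2.80 (-4.32 to -1.28), of opposite sign (Fisher's exact p = 1.78e-10 and 1.58e-05). Since a Rad21 region needed both libraries, sites with a peak of the first library alone (17 of the 31) do not count as Rad21 regions above. This comparison of single Rad21 libraries was chosen after seeing the data.

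**Figure D2:**
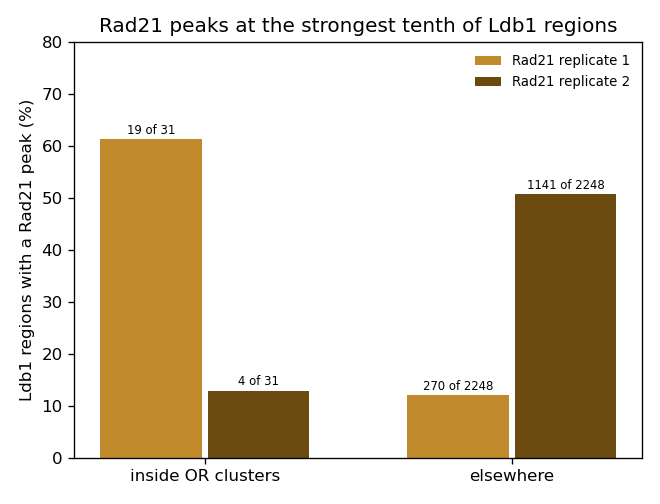
Share of the strongest 10% of control Ldb1 regions that held a Rad21 peak, in percent, inside OR clusters and elsewhere, for each Rad21 library. Replicate 1 had peaks at 19 of 31 regions inside clusters and replicate 2 at 4 of 31, while elsewhere replicate 2 had the higher share.

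Ldb1 in neurons without Lhx2 was then compared with control neurons, as a test of how far Ldb1 binding needs this partner. Most control regions had no peak in the KO lists: 2999 of 22789 (13.2%) had one in at least 1 KO library, 12.7% in the first and 2.17% in the second, and 383 (1.68%) in both. List length set much of these counts. Control lists limited to 4290 peaks, which helped define the regions, had a peak at 18.8% of them. At 542 peaks the control lists had one at 2.37% to 2.38%. The comparison fixed beforehand, the share of regions shared by 2 control libraries that was found among the 542 top peaks of a library, gave no difference past the threshold (2.79% against 3.19% ± 0.63, SD, n = 3, exact permutation p = 0.4, two-sided), but it is bounded by the 542 peaks and so could hardly differ. The 542 strongest control regions were then sought among the same top peaks, a comparison chosen after seeing the data. Control libraries, each set against regions of the other 2, recovered 89.0% ± 1.66 (SD, n = 3), and the KO libraries 19.4% and 36.9%. The difference of -60.8 percentage points was larger than the spread between libraries, but an exact permutation test of 2 against 3 libraries cannot go below its p of 0.1. Of the strongest 10% of control regions, 36.0% had a peak in the first KO library and 14.7% in the second. Control lists limited to the same lengths, from which the bins were made, gave 100% at 4290 peaks and 23.7% to 23.8% at 542 peaks. With the second KO library left out the lists could be 4290 peaks long, and the difference in the comparison fixed beforehand was -10.3 percentage points (exact permutation p = 0.25, the smallest possible). KO peaks lay more often within 1 kb of a gene end (22.5% against 11.3% ± 2.63, SD, n = 3). They also lay more often at Rad21 regions (12.5% against 3.84% ± 0.266, exact permutation p = 0.1 for both comparisons). Both comparisons used control lists at full length, not matched to the KO lists in length or peak strength. Strong control regions held Rad21 peaks more often than control regions in general. Outside OR clusters the second Rad21 library had a peak at 50.8% of the strongest 10% and at 23.4% of all. Whether the excess of KO peaks at Rad21 regions goes beyond that of strong control sites was not tested. Of the KO peaks outside control Ldb1 regions, 44.5% and 52.1% overlapped a CTCF or Rad21 peak. The share in control libraries was 19.2% to 24.8%, but over another set, the peaks outside regions shared by the other 2 control libraries. In the first control library this set held 10046 peaks, although 22222 of its 24877 peaks lay in control Ldb1 regions. The KO and control shares are therefore not directly comparable, and their difference was not tested.

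**Figure D3:**
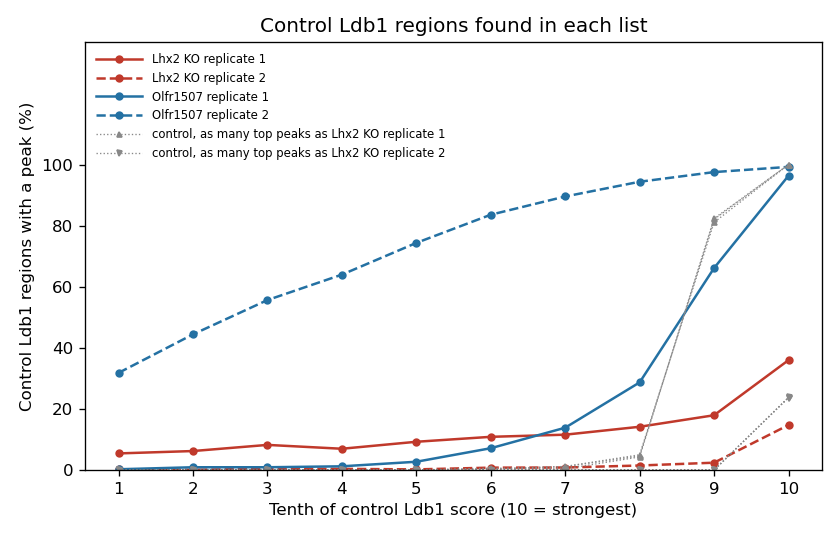
Share of control Ldb1 regions with a peak in each Lhx2 KO and Olfr1507 list, in percent, against the control score in 10 bins of equal size (10 is the strongest). Grey lines are control lists limited to as many top peaks as each KO list, and show what list length allows, since the bins were made from these libraries. In the strongest bin the first KO list held 36.0% of the regions and the second 14.7%.

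**Figure D4:**
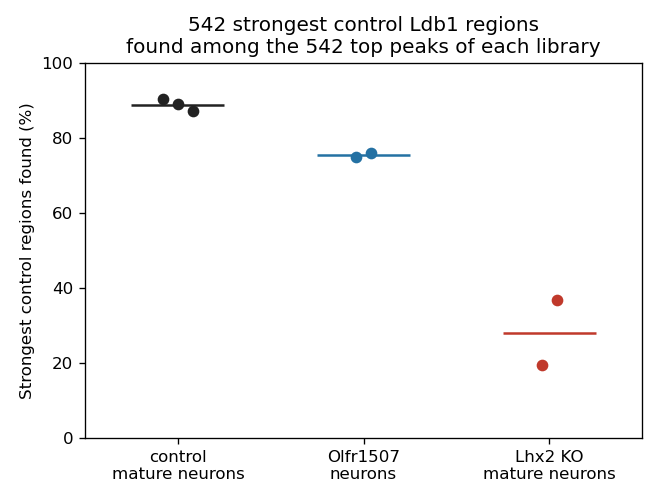
Share of the 542 strongest control Ldb1 regions found among the 542 top peaks of each library, in percent. Points are libraries and lines are group means. Control libraries lie at 89.0% on average, Olfr1507 libraries at 75.5% and KO libraries at 28.2%.

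Strong regions without a peak in either KO library lay 11.7 kb from Efr3b (chromosome 12, 4050844 to 4051188), 28.3 kb from Ccdc90b, 21.1 kb from Nek6 and 2.99 kb from Sema6a, and within Cadps2, Fbxo16 and Herc3. Others lay near Med30 (6.58 kb) and Ercc6l2 (69.6 kb), and each of these regions had a peak in both Olfr1507 libraries. Near Lhx2, 1 of 4 regions had a peak in the first KO library and 0 in the second. Around Ebf1 the counts were 2 and 0 of 26, and around Plxna4 2 and 2 of 32. Regions near olfactory transduction genes were found more often than others, 38 of 130 (29.2%) against 13.1% (log2 odds ratio 1.46, 95% interval 0.91 to 2.01, exact adjusted p = 1.45e-05 over 11 lists; within bins of control score 1.13, permutation adjusted p = 0.00770). Of these, 37 were found in the first KO library and 5 in the second; Gng13 had its 1 region in both, Omp both of its regions in the first library only, and Adcy3 3 and 1 of 10. None of the other 10 lists passed the adjusted threshold.

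The strongest OR cluster regions were among those found. Of the 10 listed above, 9 had a peak in both KO libraries, the exception being the region 7.85 kb from Olfr139, which had a peak in neither. The region with the highest score in the KO lists lay on chromosome 2 from 90414300 to 90414558, 12.6 kb from Olfr1274. Over all 167 regions in OR clusters, 35 (21.0%) had a peak in at least 1 KO library against 13.1% elsewhere (log2 odds ratio 0.81, 95% interval 0.27 to 1.35, Fisher's exact p = 0.00540, two-sided). Regions compared only with others of like control score gave 0.64 (permutation p = 0.0554), which no longer passed the threshold. Within the same bins the second KO library alone gave 2.40 and regions found in both libraries 2.63 (permutation p = 0.0001 for each, the smallest possible). Control lists limited to 542 peaks gave 1.80 to 2.11 there (permutation p from 0.0001 to 0.0007), so passing this test was not particular to the KO. The first KO library alone gave 0.60 within these bins (permutation p = 0.0675), and control lists limited to 4290 peaks gave -0.57 to 0.95. Without score bins the first KO library alone gave 0.77 and the second alone 2.58, and control lists limited to the same lengths, which helped define the regions, also held more OR cluster regions than others, 27.5% to 29.9% against 18.7% at 4290 peaks and 9.58% to 10.8% against 2.32% to 2.33% at 542 peaks, beside 19.8% and 11.4% in the KO libraries. OR clusters took 0.932% of the peaks of the first KO library and 3.51% of the second, against 0.728% ± 0.040 (SD, n = 3) in control libraries. The mean difference of 1.49 percentage points rested mostly on the second library (0.204 without it and 2.78 without the first; exact permutation p = 0.1 with both, the smallest possible).

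In neurons sorted on Olfr1507 most control Ldb1 regions were found. The longer list held a peak at 73.5% of them and the shorter list at 21.8%, and 73.7% had a peak in at least 1. The 542 strongest control regions were recovered at 75.0% and 76.0%, below all control libraries (exact permutation p = 0.1, two-sided, the smallest possible for 2 against 3). The 5 strongest regions, near Fam53a, Ankrd10 and within Zfp64, Cmip and Lingo2, were also strong in control neurons, and each of the 10 strongest OR cluster regions of control neurons had a peak in both libraries. OR clusters took 0.785% and 0.612% of the peaks, not distinguishable from control (difference -0.030 percentage points, exact permutation p = 0.8).

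Ldb1 regions close to OR genes were found less often in the Olfr1507 lists than regions elsewhere. Regions within 10 kb of OR genes had a peak at 34 of 63 (54.0%) against 73.7% of other regions (log2 odds ratio -1.26, exact adjusted p = 0.00490 over 11 lists, and permutation adjusted p = 0.00110 within score bins). All 34 were in the longer list, and the shorter list had a peak at 10 of the 63. Over the 167 regions in OR clusters the share was 68.3% against 73.7% (log2 odds ratio -0.38, 95% interval -0.85 to 0.09, Fisher's exact p = 0.113). The shorter list alone gave 0.18, and -1.55 within bins of control score (permutation p = 0.00410), where control lists of that length gave values from -1.16 to 0.96. Against regions of like control score the log2 odds ratio over both lists was -0.76 (permutation p = 0.00600), past the threshold. Regions near olfactory transduction genes were found at 112 of 130 (49 in the shorter and 112 in the longer list, 86.2%, exact adjusted p = 0.00490), a difference that was lost within score bins (permutation adjusted p = 0.768), and regions near axon guidance genes at 165 of 237 (62 and 162 by list, 69.6%, exact adjusted p = 0.292, and permutation adjusted p = 0.00110 within score bins). Of the 10 regions near sustentacular and gland genes 5 were found, 3 of them in the shorter list (exact adjusted p = 0.292, and permutation adjusted p = 0.0433 within score bins).

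The locus of Olfr1507 itself (chromosome 14, 52489935 to 52495695 in mm10) had no control Ldb1 region within 10 kb. A single strong region lay on its higher-coordinate side, from 52547934 to 52548271 in the first control library, 52.2 kb from the gene, and had a peak in all 7 Ldb1 libraries. The score of its peak stood at the percentiles 98.2, 98.7 and 97.2 of the control lists, 90.1 and 96.7 of the Olfr1507 lists, and 74.5 and 67.5 of the KO lists. These lists range from 542 to 28879 peaks, so the percentiles cannot be compared between them. A lower percentile in a short KO list need not be a lower rank. In the second Olfr1507 library a further peak lay 56 bases from the same end of the gene, from 52495752 to 52496131, with a score of 27, at the percentile 50.1 of its list. No control library and not the first Olfr1507 library had a peak within 1 kb of Olfr1507. The first KO library had one 2.18 kb away on the lower-coordinate side. In that second Olfr1507 library 3 of 1109 OR genes had a peak within 1 kb, Olfr1507, Olfr1357 and Olfr183, and Olfr1357 and Olfr183 also had one in each control Ldb1 library; Olfr1357 was named after its values were seen.

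**Figure D5:**
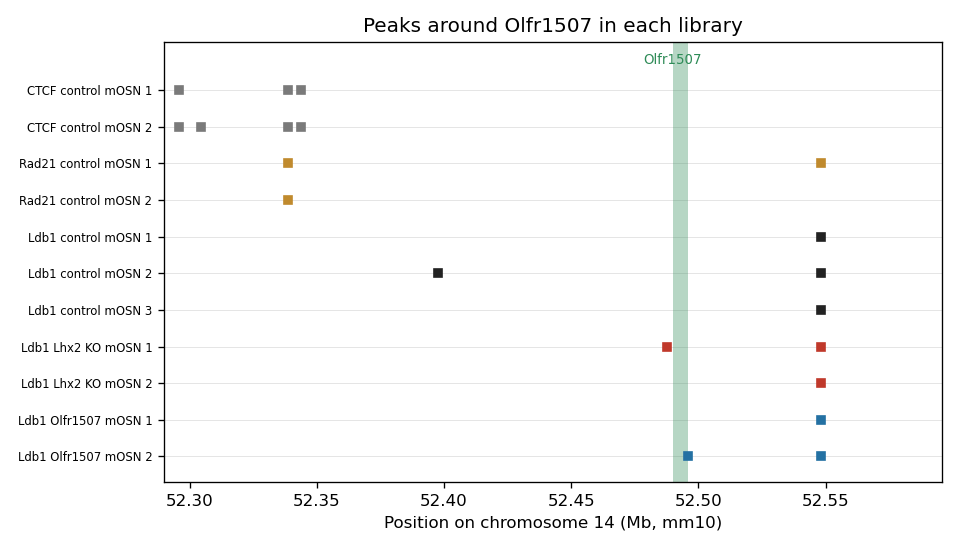
Positions of peaks on chromosome 14 around Olfr1507 (green band) in each of the 11 libraries, in Mb of mm10; each square is 1 peak. The region 52.2 kb beyond the higher-coordinate end of the gene has a peak in all 7 Ldb1 libraries and in the first Rad21 library, and the peak next to the gene is in the second Olfr1507 library alone.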

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

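Each result here lies outside every comparison of the report. Peaks on contigs outside the main chromosomes were more numerous than the limit of 3 that a count of 0 allows in both CTCF libraries. They were 8 of 27617 and 7 of 34217 peaks. Nothing in the design makes 0 the count to expect on contigs, so the limit serves only to flag these libraries. In the first Lhx2 KO library 5 such peaks stood against at most 2 in a control Ldb1 list, although its list was shorter. These counts were not examined further.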

How the results depend on the processing

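Of the alternatives given here, the comparison with random genes of the same length was chosen after the results were seen, as were the tests on the strongest 10% of regions. Over 181 recomputed values, 159 kept their direction and their side of the threshold, or stayed within the spread set for values without a test. This tally overstates stability. Permutations of libraries allow no p below 0.1, so those values could not change their side of the threshold. The 181 values also include control lists limited to KO or Olfr1507 length, which hold no peaks of those groups. The excess of Rad21 regions at CTCF regions kept its direction and its call under every alternative run. Against all bound regions as background, the log2 values for OR clusters were 0.034 for Ldb1, 0.13 for CTCF and 0.20 for Rad21, and those for Ldb1 regions at CTCF and at Rad21 were -4.25 and -2.47; all 5 had the opposite sign to the main values, because this background holds only sites bound in some library. The higher share of OR cluster regions found in Lhx2 KO neurons was 0.64 within bins of control score, no longer past the threshold. The lower share in Olfr1507 neurons passed the threshold for the top-scoring 50% of each list (-0.95, Fisher's exact p = 0.00227) and for OR clusters without flanks (-0.67, Fisher's exact p = 0.0417). It also passed within score bins (-0.76, permutation p = 0.00600). The sign turned, short of the threshold, for regions with a peak in both libraries (0.19). Control lists limited to the length of the longer Olfr1507 list gave 0.16. They hold no Olfr1507 peaks, so this is a level for control neurons and not a changed Olfr1507 value. With single libraries left out the Olfr1507 value ranged from -0.71 to 0.18, above 0 only without the second Olfr1507 library. Without the first control library it was -0.70 (Fisher's exact p = 0.0488). For these changes in the KO and Olfr1507 comparisons the cause was not tested. With gene bodies extended by 50 kb, 6 gene lists passed in place of 10. Only the number passing was kept, so the lists lost at 50 kb are not named. With the 10 kb window, 8 lists passed against genes of the same length. The cause was tested for neither change.

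Leaving out 1 library moved several values by over 1.5 times. These include the KO result in OR clusters (2.58 without the first KO library), the KO difference in OR cluster share (2.78 without the first, 0.204 without the second) and the difference in recovered regions (-10.3 without the second KO library, where the lists compared also grew from 542 to 4290 peaks, and -0.193 without the third control library). The Olfr1507 difference in OR cluster share ranged from -0.116 to 0.0571, above 0 only without the second Olfr1507 library. The log2 excess was 6.39 for Rad21 at CTCF and 4.87 for Ldb1 at Rad21 without the first Rad21 library, and 3.28 for Ldb1 at CTCF without the first CTCF library. Control Ldb1 regions numbered 15055 without the second control library, and the share of them found was 2.17% without the first KO library and 21.8% without the second Olfr1507 library. The labels number the libraries of each group without saying that a number marks a shared animal or day. With the replicate number as a block the differences in OR cluster share were 1.51 for KO and -0.00762 for Olfr1507, and the difference in recovery was -0.768; no call changed, and 2 pairs cannot pass a threshold. The motif search, which needs a genome sequence, and the gene lists by start site within 5 kb, which need strand, were not run. Depth is unknown, so a region missing from a short list cannot be read as unbound.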

Other observations

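The tests of the Rad21 and Olfr1507 patterns, and the comparison of the strongest regions among equal numbers of top peaks in the KO pattern, were chosen only after the result was seen.

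Hox genes were poor in Ldb1 regions and rich in CTCF regions. Of 39 Hox genes 30 had a CTCF region within 10 kb (log2 odds ratio 1.36, Fisher's exact adjusted p = 0.0205 over 15 lists), while 2, Hoxc6 and Hoxc8, shared a single Ldb1 region. The test counts each Hox gene as independent, but neighbouring genes can share a CTCF region in the same way. The number of separate CTCF regions behind the 30 genes was not counted, so this p-value may be too small. OR genes had few of either, 40 of 1109 with CTCF and 16 with Rad21.

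Few control Ldb1 regions had a peak in the Lhx2 KO lists. List length accounts for much of the number found: control lists limited to 4290 peaks held 18.8% of the regions, beside 12.7% in the first KO library. At 542 peaks they held 2.37% to 2.38%, beside 2.17% in the second. Shorter lists alone do not account for which regions were found: among equal numbers of top peaks the KO libraries held 28.2% of the strongest control regions and control libraries 89.0%. Bounds set beforehand on another value, the share of KO peaks in regions shared by 2 control libraries, were met in neither direction. They ask for both KO libraries. As a mean over the pairs the share was 59.2% and 88.3% (67.4% and 91.1% in the control regions used elsewhere), against 99.1% and 99.9% in equally short lists of the third. Whether background sites make up part of the KO lists stays open: at least 44.5% of the KO peaks outside control regions overlapped a CTCF or Rad21 peak, but so did 61.0% and 65.8% of those inside. Noisier ranks from weaker enrichment may add to it, since 29.3% of the top peaks of the second KO library were among as many of the first, and 36.3% to 37.3% among those of control libraries. Loss of Ldb1 binding without Lhx2 stays open and untested, because enrichment was not measured and a difference in it between the KO and control libraries would be confounded with genotype.

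The first Rad21 library had peaks at the strongest Ldb1 regions in OR clusters that the second lacked. Carry-over of Ldb1 fragments from the libraries used here would reach strong regions everywhere, but 2.40% of those outside OR clusters (54 of 2248) had a peak of the first Rad21 library alone, against 17 of 31 inside, a contrast widened by the second library, which had peaks at 50.8% of the strong regions outside. Among strong regions without a peak of the second library the first had one at 4.88% outside (54 of 1107) and at 17 of 27 inside, so carry-over from these libraries stays a poor account. For weak peaks near the calling threshold, 6.47% of first-library peaks of the same scores elsewhere were missing from the second, against 22 of 26 here. Those peaks were matched on score alone. Of all first-library peaks 9436 of 10487 lay at a CTCF region, whereas none of the 10 strongest OR cluster regions held a CTCF peak. The comparison therefore cannot decide on weak peaks at sites without CTCF, which may be the source. So may carry-over from a library not analysed here, a difference in the cells or cohesin at these sites, and none of these was tested.

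The peak next to Olfr1507 was in the second library of Olfr1507 neurons and in no control library. Peaks within 1 kb of an OR gene were rare in that library, at 0.271% of OR genes, Olfr1507 included. They were rare in every library, from 0 to 9 of 1109 OR genes, so the test could hardly have come out otherwise. Olfr1507 is also longer (5.76 kb) than the median OR gene (0.951 kb), which widens its window. The rarity makes a chance peak at this gene less likely but does not exclude it. Its absence from the first Olfr1507 library may come from the shorter list, in which 1.46% of second-library peaks of similar score (23 of 1573) were found. The reporter allele, open chromatin at a transcribed gene and Ldb1 binding at the active receptor gene stay open, as the input libraries were not analysed here.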
